A study of Homo sapiens with 3 samples.

How the data were processed

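RNA was measured in 3 samples of sorted human cells at day 21 of motor neuron differentiation, 1 library per group: SHH GFP-high, S+P GFP-high and S+P GFP-off. Per the labels' protocols, total RNA was taken with Trizol and amplified with a NuGEN kit before sequencing. The GFP-off sample carries a cell-type label of motor neurons while the design text describes it as other cells, so it is called the GFP-off fraction here.

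The deposited table gives RPKM (reads per kilobase of gene length, scaled to library size) per gene and library, per the file headers, with a gene length and gene coordinates. Reads were aligned with Bowtie per the submitters' processing notes; its version, the genome build, the gene annotation and the counting rule are not given in the sources used here. The design text speaks of an early analysis on part of the reads and of a fuller one; which of these the table holds is not given in the sources used here. Of 50338 rows, 1354 had no start, length or value and were left out, which left 48984 rows and 44551 symbols. RPKM was below 0 in at least 1 library in 2343 rows, 1487 of them with a gene length under 200 bases; these values were set to 0. How negative values arose is not given in the sources used here, and reads derived from RPKM are therefore called net reads.

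The product of RPKM and gene length was a whole multiple of a fixed step in 100% of nonzero values, within a tolerance of 0.01 of a step, in each library. The step gave net reads per gene and a library total of 40084322 reads for SHH GFP-high, 25052310 for S+P GFP-high and 32422674 for S+P GFP-off. These totals follow from reading the step as 1 read and are not stated by the authors. Net reads in genes came to 50.0%, 51.5% and 58.0% of those totals. The mitochondrial 12S and 16S ribosomal RNA rows held 20.68% (95% exact Clopper-Pearson interval 20.67% to 20.69%), 20.33% (20.31% to 20.34%) and 24.71% (24.70% to 24.73%). For a gene of 2 kilobases, 3 reads, the most that a count of 0 allows, correspond to 0.0374, 0.0599 and 0.0463 RPKM. Intervals and floors cover counting error only.

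File coordinates count from 1 with an end 1 base past the gene, as 35 of 37 mitochondrial genes matched GRCh38 in both ends on that reading. None of 37360 nuclear genes shared a start or end with GRCh38 in GENCODE 29, so the nuclear coordinates are of another build, and reference coordinates were not used. GENCODE 29 and its name table served only for current symbols and for GC content; 37254 IDs had a current symbol.

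For each comparison a gene entered where RPKM was at least 1 in at least 1 of the 2 libraries. The log2 ratio of RPKM + 1 was computed without further scaling, and genes at or past 2-fold were counted. Where a symbol had several rows, the row with the highest mean RPKM was used. With 1 library per group no test of conditions was made. Fold intervals compare 2 libraries, not conditions, and are exact conditional binomial intervals of net reads at 95%; a fold against 0 reads used a floor of 3 reads per library. For each of 31 gene lists, the median log2 ratio was set against 10000 random lists of the same size matched on expression in 20 bins, as a description of these libraries; lists with fewer than 3 measured members have no such percentile. Of 442 listed symbols, 6 had no value. Pattern lists take pseudogenes too.

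The lists, comparisons, thresholds and most alternatives were set before the data were examined. Named genes were the 12 largest and 12 smallest log2 ratios among genes reaching 5 RPKM in the higher library for S+P GFP-high against S+P GFP-off and for SHH against S+P GFP-high, up to 4 leading members of each list, members needed to state that 2-fold was not passed, and 12 fixed genes of motor neurons, HOX and Hedgehog signalling. Symbols that are only clone or reading frame codes, small RNAs and ribosomal RNAs were not named, and a few genes that the rule takes are not reported here. Further genes are named in the closing part and were chosen after their values were seen.

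For the genes shared by both comparisons with GFP-off, 100 sets of unchanged libraries were simulated with noise drawn from the differences between the GFP-high libraries at like expression. Alternatives were pseudocounts of 0.1 and 5, no filter, a filter of 5 RPKM, median-ratio and upper-quartile scaling, leaving out the 100 most abundant genes, the mean of rows per symbol and a 4-fold threshold. Added after seeing the data were net reads of at least 20 with 0.5 reads added, and a requirement that the whole counting interval lie past 2-fold. The steps were tested on simulated reads drawn from the real means and totals over 44551 genes with 200 genes changed. The changed genes were drawn from those at 2 RPKM or more over the pooled libraries, and the noise was counting noise only. Recovery of lower genes and calls from amplification noise were therefore not tested. For S+P GFP-high against S+P GFP-off, 94% of genes changed 3-fold and 100% of those changed 4-fold were called, and 9 of 10955 unchanged entering genes. For SHH against S+P GFP-high the shares were 100% and 100%, with 9 of 10912, and for SHH GFP-high against S+P GFP-off 96% and 100%, with 3 of 10905. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.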

Results

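Motor neurons were made from HUES 3, an established human embryonic stem cell line, carrying a green fluorescent protein (GFP) reporter of HB9 (MNX1), a transcription factor gene of motor neurons. Cultures received either Sonic hedgehog protein (SHH) or a pair of smoothened agonists, SAG and purmorphamine (S+P). At day 21 cells were sorted by GFP, and RNA was sequenced from 3 samples: the GFP-high fraction of the SHH protocol, the GFP-high fraction of the S+P protocol and the GFP-off fraction of the S+P protocol. Each group held 1 library, so no difference had a replicate check, no test between conditions was possible, and no p-value is given. Library totals, inferred from the steps between the values, were 40084322 reads for SHH GFP-high, 25052310 for S+P GFP-high and 32422674 for S+P GFP-off. Read counts given without a fold are not scaled to these totals. Folds in brackets with an interval come from net reads per library total, and the 95% exact interval covers counting error only, since amplified reads are not independent molecules. Log2 ratios are on the scale of log2(RPKM + 1), which understates the ratio of low genes. Measured members of a list are those at 1 RPKM or more in 1 of the libraries; counts by net reads take instead the members with at least 20 reads in 1 of them.

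In S+P cultures, genes of postmitotic neurons were higher in the GFP-high than in the GFP-off library, and genes of neural progenitors, dividing cells and mesenchyme were lower. STMN2, a microtubule regulator of growing axons, stood at 267 RPKM against 21.4 RPKM (12.5-fold, 11.8 to 13.2), the largest log2 ratio among genes reaching 5 RPKM, 3.58. The lowest was that of CTGF (now CCN2), a matricellular protein gene, at 11.5 RPKM against 73.9 RPKM, a log2 ratio of -2.59. Of 11747 genes that entered, 404 were at least 2-fold higher and 604 at least 2-fold lower. This comparison asks how reporter-positive cells differ from the reporter-negative cells of the same protocol.

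**Figure D1:**
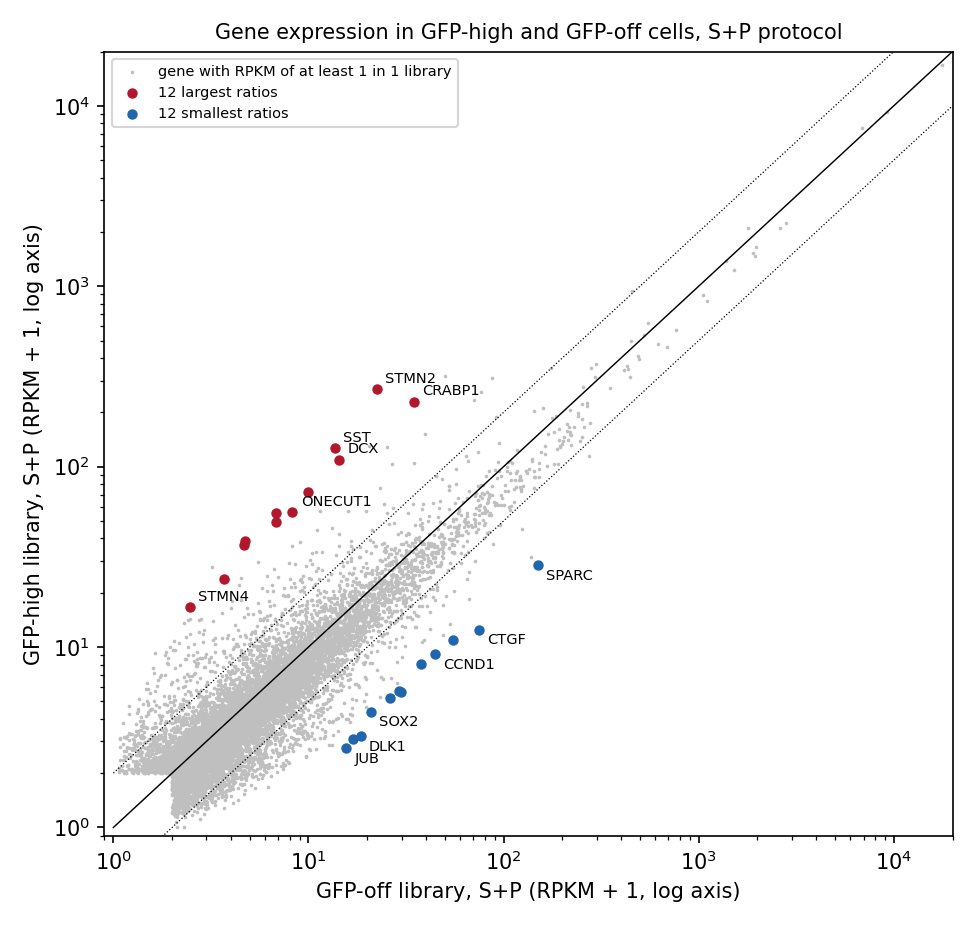
RPKM + 1 of each gene in the S+P GFP-off library (horizontal, log axis) and the S+P GFP-high library (vertical, log axis), for genes with RPKM of at least 1 and at least 20 reads in 1 of the libraries. The solid line marks equal values and the dotted lines 2-fold; STMN2 lies at 267 RPKM against 21.4 RPKM and CTGF at 11.5 RPKM against 73.9 RPKM.

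MNX1, the gene whose reporter was sorted (ENSG00000130675, chromosome 7, 156479506 to 156496000 in the file's coordinates, minus strand, build not given in the sources used here), had 50 net reads in S+P GFP-high and 3 in S+P GFP-off, a 21.6-fold ratio with an interval of 6.97 to 108. In SHH GFP-high it had 66 reads. All of these lay below 1 RPKM, so MNX1 did not enter the 2-fold counts.

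The median log2 ratio of all entering genes was -0.17 in this comparison, and median-ratio scaling moved it to -0.01. List medians for S+P GFP-high against S+P GFP-off are therefore given relative to the median of all genes. Of 7 measured motor neuron transcription factors, 5 were at least 2-fold higher and none lower, with a relative median of 2.27, above all 10000 random lists of like expression. That median was 1.25 with a pseudocount of 5 RPKM and 0.48 without a filter, when 12 members entered. The pan-neuronal list had a relative median of 2.22, and the random lists were matched on expression only. The list median therefore does not set motor neurons apart from other neurons. ONECUT1 had a log2 ratio of 2.76, ONECUT2 2.62, ISL1 2.30 and EBF3 2.09. ISL1, a LIM homeodomain factor of motor neurons, stood at 8.06 RPKM against 0.844 RPKM (9.55-fold, 7.48 to 12.3). LHX3, which acts with ISL1 in motor neuron specification, had 16 reads against 5 (4.14-fold, 1.45 to 14.5).

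Of 6 measured genes of cholinergic transmission, 4 were at least 2-fold higher and none lower. The relative median was 1.48, above all 10000 random lists. Without a filter it was 0.77, over 12 members, and by net reads 8 of 10 were higher. The list of other transmitters also rose by net reads, with 5 of 6 higher. Its net-read median was 1.88, against 1.44 for cholinergic genes, both before subtracting the median of all genes. SLC5A7, the high-affinity choline transporter, had a log2 ratio of 2.26, and SLC18A3, the vesicular acetylcholine transporter, 2.19. The nicotinic receptor subunits CHRNB4 and CHRNA3 stood at 1.34 and 1.26. CHAT, which makes acetylcholine, lay below 1 RPKM but had 74 reads against 7 (13.7-fold, 6.32 to 35.2).

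Among 25 measured pan-neuronal genes, 21 were at least 2-fold higher and none lower, with a relative median of 2.22, above all 10000 random lists, and of 1.34 with a pseudocount of 5 RPKM. After STMN2, the largest log2 ratios in the list were those of SYT4 (2.98), DCX (2.93) and NCAM1 (2.86). NEFH, the heavy neurofilament chain, stood at 2.42 RPKM against 2.12 RPKM and did not pass 2-fold. Voltage-gated channels had 3 of 10 measured members at least 2-fold higher and none lower, led by SCN3A at 2.09. By net reads 13 of 17 channels were higher, with a pseudocount of 0.1 RPKM 7 of 10, and with a pseudocount of 5 RPKM none. In the axon guidance and trophic receptor list, 10 of 25 were at least 2-fold higher and 3 lower: SLIT3 had a log2 ratio of 2.69, PLXNA4 1.53 and RET 1.52, while CXCR7 (now ACKR3) had -1.86. By net reads 16 of 31 in that list were higher and 3 lower, and with a pseudocount of 5 RPKM 1 of 25 in each direction. The remaining genes among the 12 largest ratios were SST (somatostatin, 3.22), GNG3 (3.03), AKAP6 (3.02), CNTN2 (2.86), STMN4 (2.76) and CRABP1 (2.72).

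HOX genes were higher in the GFP-high library in paralog groups 1 to 5, where all 15 members had positive log2 ratios and 3 passed 2-fold, against 6 with median-ratio and 5 with upper-quartile scaling: HOXB5 (1.82), HOXB1 (1.37) and HOXD3 (1.16). HOXA5 stood at 60.9 RPKM against 37.8 RPKM. The relative median was 0.85, above all 10000 random lists. Of groups 6 to 9, 4 genes were measured and none passed 2-fold, while by net reads 2 of 6 were higher; HOXB9 was the lowest measured at -0.43. HOXC6 had 24 reads against 5 (6.21-fold, 2.32 to 20.8), and HOXC8 had 7 against 5. No gene of groups 10 to 13 reached 1 RPKM or 20 reads in either library.

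None of 10 measured limb column and pool genes passed 2-fold, though 2 were higher with median-ratio and 1 with upper-quartile scaling, 1 was lower with a pseudocount of 0.1 RPKM and 2 of 12 were lower by net reads. FOXP1, a factor of limb-innervating motor neurons, stood at 8.96 RPKM against 5.67 RPKM (1.58-fold, 1.49 to 1.67). ALDH1A2 had 9 reads in each library. In the medial, hypaxial and preganglionic column list, 1 of 4 was lower: the row named MDS1, reached from MECOM through the reference names, at -1.62.

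Progenitor and cell cycle genes were lower in GFP-high cells. Of 18 measured neural progenitor genes, 9 were at least 2-fold lower and none higher, with a relative median of -0.82, below all 10000 random lists. The median was -1.29 by net reads and -0.43 with a pseudocount of 5 RPKM, which left 3 lower. SOX2 stood at 3.38 RPKM against 19.9 RPKM (log2 ratio -2.25), VIM had -2.14, NOTCH3 -1.77 and PROM1 -1.76. All 26 cell cycle genes had negative log2 ratios, 15 of them past 2-fold, against 23 by net reads and 3 with a pseudocount of 5 RPKM, with a relative median of -0.90, below all 10000 random lists. TYMS had -1.79, MCM3 -1.55, RRM2 -1.54 and MKI67, a protein of dividing cells, -1.31. Replication-dependent histones, a family whose near-identical copies can share reads, had 16 of 34 measured members at least 2-fold lower, against 3 with a pseudocount of 5 RPKM, and none higher.

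Hedgehog pathway genes had 2 of 7 measured members at least 2-fold lower, GLI3 (-1.60) and GLI2 (-1.54), and none higher; without the 100 most abundant genes 3 of 8 were lower, with a pseudocount of 0.1 RPKM 4 of 7, and by net reads 3 of 12 were higher and 6 lower. PTCH1, the Hedgehog receptor and target, stood at 10.4 RPKM against 10.9 RPKM. GLI1, a direct target of the pathway, had 2 reads against 31, a ratio of 0.0835 with an interval of 0.00968 to 0.328. Of 6 measured ventral spinal progenitor genes, IRX3 alone passed 2-fold, at 1.42, with a relative median of 0.33, which was -0.092 without the 100 most abundant genes. By net reads 1 of 10 was higher and 5 were lower, with a relative median of -0.81.

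Markers of cell types other than neurons lay mostly on the GFP-off side. In the mesenchyme and neural crest list, 4 of 8 measured genes were at least 2-fold lower, against 1 with median-ratio or upper-quartile scaling, and none higher, led by ACTA2 (-1.46), POSTN (-1.09) and COL1A1 (-1.07). By net reads 12 of 14 were lower, with a pseudocount of 0.1 RPKM 7 of 8, without the 100 most abundant genes 5 of 9, and with a pseudocount of 5 RPKM none. Of 7 measured glial genes, 3 were lower, among them GJA1 (3.18 RPKM against 15.7 RPKM) and SLC1A3 (-1.98). SLC1A2, a glutamate transporter, was higher at 2.67. All 3 measured epithelium and endoderm genes were at least 2-fold lower: KRT18 (-1.85), GATA6 (-1.26) and KRT8 (-1.26). The endothelial receptor gene KDR had -1.82, the only measured gene of the blood and endothelium list. Among pluripotency genes, 1 of 5 passed 2-fold, DPPA4 at -1.31.

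The remaining lists varied in the size and direction of their differences. In the retinoic acid response list, CRABP1 (2.72), CRABP2 (2.34) and RET (1.52) were higher and CYP26B1 lower (-1.18), the last not with median-ratio scaling. The relative median of 0.66 was 0.086 without the 100 most abundant genes, 0.0094 by net reads and -0.017 without a filter. Of other transmitter genes, SLC18A2 and DDC were measured and neither passed 2-fold (0.93 and 0.76); by net reads 5 of 6 were higher and none lower. Immediate early and heat shock genes had 3 of 10 lower, against 1 with median-ratio or upper-quartile scaling, 5 with a pseudocount of 0.1 RPKM or without the 100 most abundant genes, and 6 of 12 by net reads: GADD45B (-1.31), ATF3 (-1.09) and EGR1 (-1.08). Hypoxia and glycolysis genes had 4 of 8 lower and none higher, led by SLC2A1 (-1.59), with a relative median of -0.67. That of the immediate early and heat shock list was -0.64, with none of its members higher. Of 18 motor neuron disease genes, KIF5A alone passed 2-fold (1.82), and 1 other was lower without the 100 most abundant genes or with a pseudocount of 0.1 RPKM, and 2 of 19 by net reads. Among 14 housekeeping genes, B2M alone passed 2-fold (-1.03), and none did with median-ratio or upper-quartile scaling. Of 79 ribosomal protein genes 1 was lower, and none with median-ratio scaling, with a relative median of -0.31, and none of 13 mitochondrially encoded genes passed 2-fold. None of 19 cholesterol synthesis genes passed 2-fold. None of the list of other spinal neurons reached 1 RPKM, but neither did MNX1 and CHAT, so this does not show them absent from GFP-high cells. By net reads 4 of 7 were higher and 1 lower, with a median of 1.13 before subtracting the median of all genes, -0.23. Read counts of some members are given in the closing part. Lower genes outside these lists included DLK1 (-2.53), JUB (now AJUBA, -2.51), GDF3 (-2.44), ZFP36L1 (-2.40), SPARC (-2.39), FAM84B (now LRATD2, -2.36), EDNRB (-2.33), GPR177 (now WLS, -2.31), CCND1 (-2.29) and TGFB2 (-2.22).

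**Figure D2:**
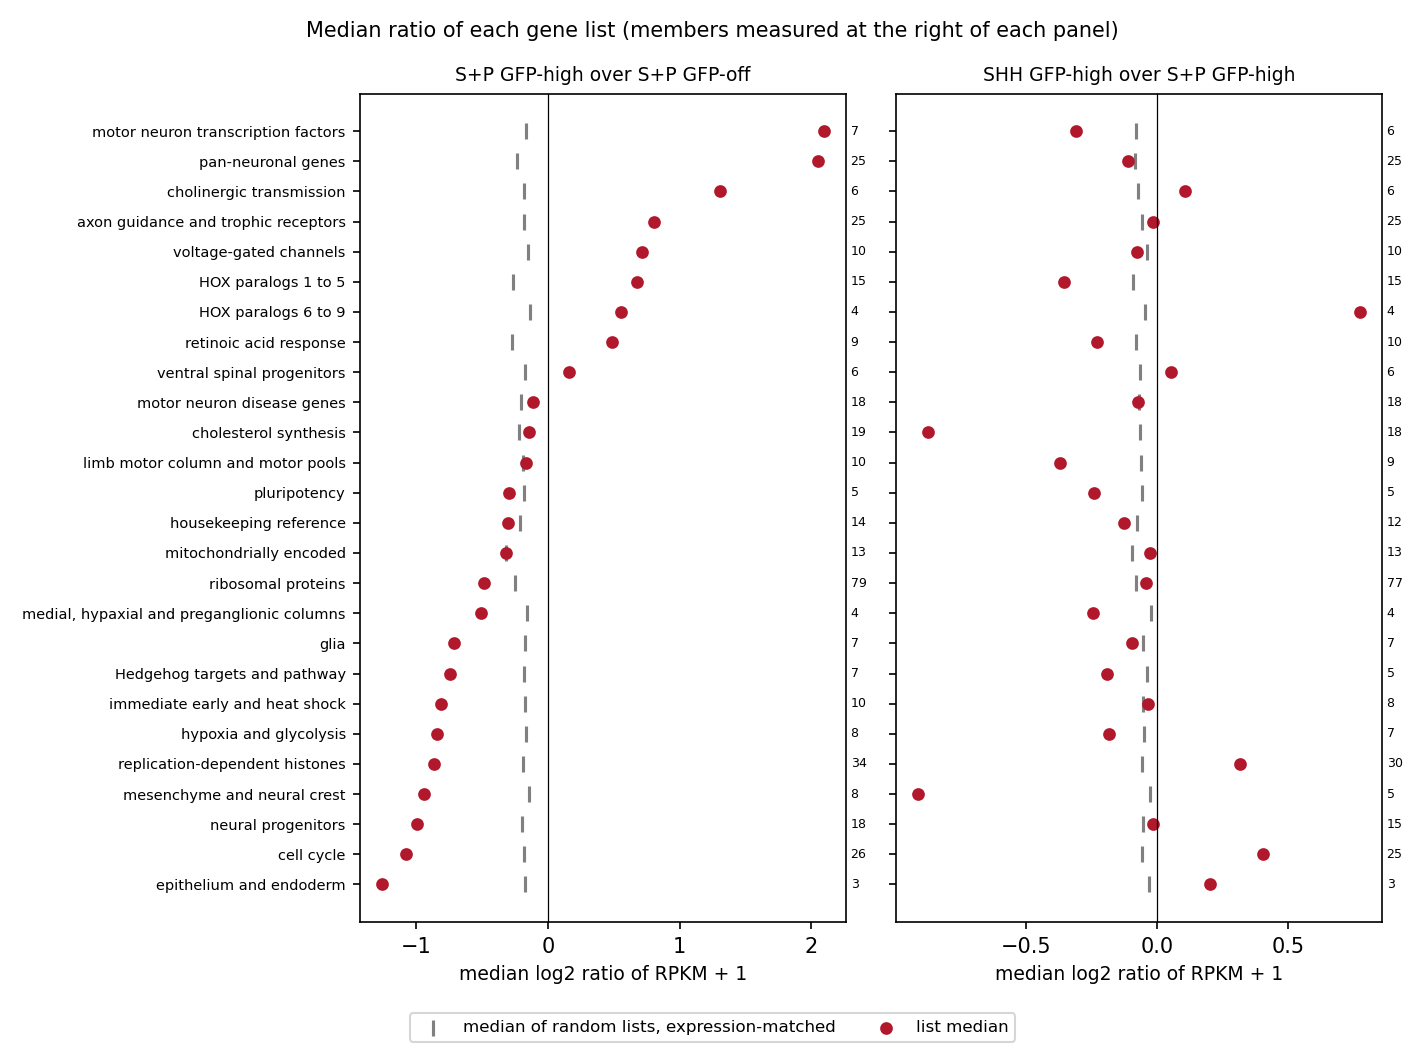
Median log2 ratio of RPKM + 1 for each gene list with at least 3 measured members in both comparisons (points), beside the median of random lists of like expression (vertical ticks); numbers at the right of each panel count the measured members. Motor neuron transcription factors lie at 2.09 in the left panel, and cholesterol synthesis genes at -0.87 in the right panel.

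The split of higher and lower calls depended on the scaling between libraries. With median-ratio scaling 523 genes were higher and 382 lower, and with upper-quartile scaling 504 and 399, against 404 and 604 with RPKM as deposited. A pseudocount of 5 RPKM gave 118 higher and 101 lower, and folds of net reads, with at least 20 reads in 1 library, gave 1123 higher and 2216 lower. The larger pseudocount also left 1 lower gene each in the epithelium and endoderm and the hypoxia lists. It left no gene past 2-fold in the Hedgehog, ventral progenitor, medial column, pluripotency, immediate early, housekeeping and ribosomal lists.

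The GFP-high libraries of both protocols were far closer to each other. Of 10953 genes that entered, 27 were at least 2-fold higher in SHH than in S+P, 40 were at least 2-fold lower, and the median log2 ratio was -0.05. Genes of cholesterol synthesis and of mesenchyme were lower in the SHH library, and HOXB9 and PHOX2A were higher. HOXB9, a posterior HOX gene, stood at 8.74 RPKM against 1.34 RPKM (6.53-fold, 5.55 to 7.73), and SST at 30.8 RPKM against 126 RPKM (0.244-fold, 0.224 to 0.265). This comparison asks whether the way the Hedgehog pathway was activated changed the reporter-positive cells; with 1 library each, protocol and culture batch cannot be told apart. A pseudocount of 5 RPKM left 2 higher and 8 lower, and folds of net reads gave 418 higher and 310 lower.

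None of 6 measured motor neuron transcription factors passed 2-fold, with a median of -0.31, which was -0.17 with median-ratio scaling and -0.11 without a filter. With upper-quartile scaling 1 of 7 was higher, and with a pseudocount of 0.1 RPKM 1 of 6. ISL1 stood at 5.94 RPKM in SHH and 8.06 RPKM in S+P (0.737-fold, 0.657 to 0.828), and NEUROD4 had the largest log2 ratio, 0.93. For MNX1 (0.825-fold, 0.563 to 1.22), CHAT (0.760-fold, 0.553 to 1.05) and LHX3 (1.80-fold, 0.998 to 3.40) the counting interval included 1. None of 6 cholinergic genes passed 2-fold; CHRNA5 and SLC18A3 had the largest log2 ratios, 0.39 and -0.39, and the list median of 0.11 turned to -0.075 when the 100 most abundant genes were left out. None of 25 pan-neuronal genes passed 2-fold, with PRPH lowest at -0.91. None of 9 limb column and pool genes passed 2-fold, with a median of -0.37, below all 10000 random lists, and of -0.16 with a pseudocount of 5 RPKM; ETV5 stood at -0.86, GFRA1 at -0.59 and FOXP1 at -0.31. None of 4 medial, hypaxial and preganglionic column genes passed 2-fold. By net reads, 1 of 10 motor neuron transcription factors was higher, 1 of 26 pan-neuronal genes lower, and of 12 limb column and pool genes 1 higher and 2 lower. A pseudocount of 0.1 RPKM gave 1 lower pan-neuronal gene and 2 lower limb column and pool genes.

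Of 15 genes in HOX groups 1 to 5, 12 had negative log2 ratios and none passed 2-fold, with a median of -0.35, below all 10000 random lists. HOXA4 stood at -0.93, HOXC5 at -0.86, HOXC4 at -0.85 and HOXA5 at -0.33. All 4 measured genes of groups 6 to 9 had positive log2 ratios, with a median of 0.77, above all 10000 random lists: HOXB9 (2.06), HOXB8 (0.94), HOXB7 (0.61) and HOXB6 (0.47). With median-ratio or upper-quartile scaling 2 of 5 measured were at least 2-fold higher, against HOXB9 alone as deposited, and by net reads 3 of 7. The median was 0.43 with a pseudocount of 5 RPKM and 0.22 without a filter, over 12 members. HOXC6 had 21 reads in SHH, the deeper library, and 24 in S+P, and HOXC8 had 0 and 7. No gene of groups 10 to 13 and none of the list of other spinal neurons entered. PHOX2A, a factor of cranial visceral motor neurons, had a log2 ratio of 1.38, at 4.21 RPKM against 1.00 RPKM, with 282 reads against 42. NKX2-2, a ventral progenitor factor, was the only 1 of 6 measured ventral progenitor genes past 2-fold, against 2 of 9 by net reads and none with a pseudocount of 5 RPKM, with 190 reads against 25 (4.75-fold, 3.12 to 7.53).

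**Figure D3:**
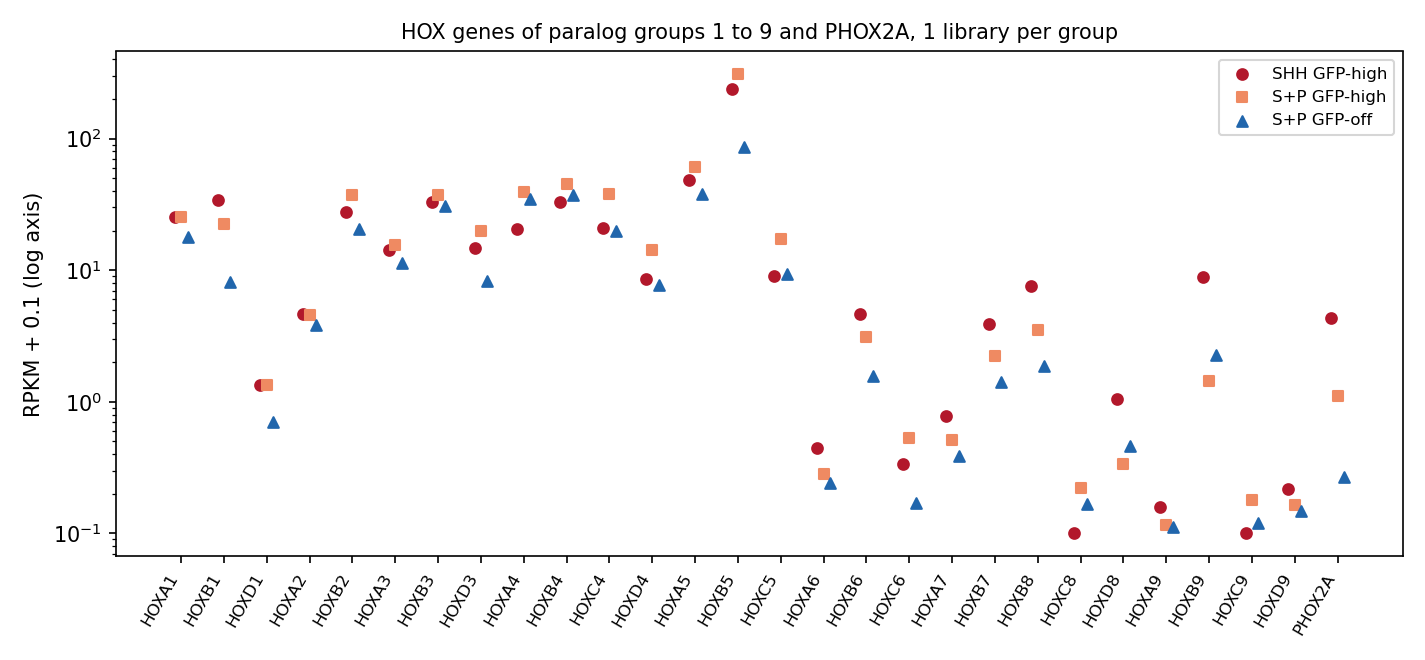
RPKM + 0.1 (log axis) of HOX genes of paralog groups 1 to 9 and of PHOX2A in the 3 libraries, 1 point per library. HOXB9 lies at 8.74 RPKM in SHH GFP-high, 1.34 RPKM in S+P GFP-high and 2.16 RPKM in S+P GFP-off.

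All 18 measured cholesterol synthesis genes had negative log2 ratios and 7 were at least 2-fold lower in SHH, with a median of -0.87, below all 10000 random lists. By net reads 14 of 20 were lower and with a pseudocount of 0.1 RPKM 13 of 18, while a pseudocount of 5 RPKM left 4, with a median of -0.49. HMGCS1, at the entry to the mevalonate pathway, stood at 27.2 RPKM against 98.6 RPKM (-1.82). SC4MOL (now MSMO1) stood at -1.41, FDFT1 (squalene synthase) at -1.38 and MVD at -1.35. ACAT2, outside the list, had -1.47. In S+P GFP-off, HMGCS1 stood at 104 RPKM and FDFT1 at 107 RPKM, close to S+P GFP-high.

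**Figure D4:**
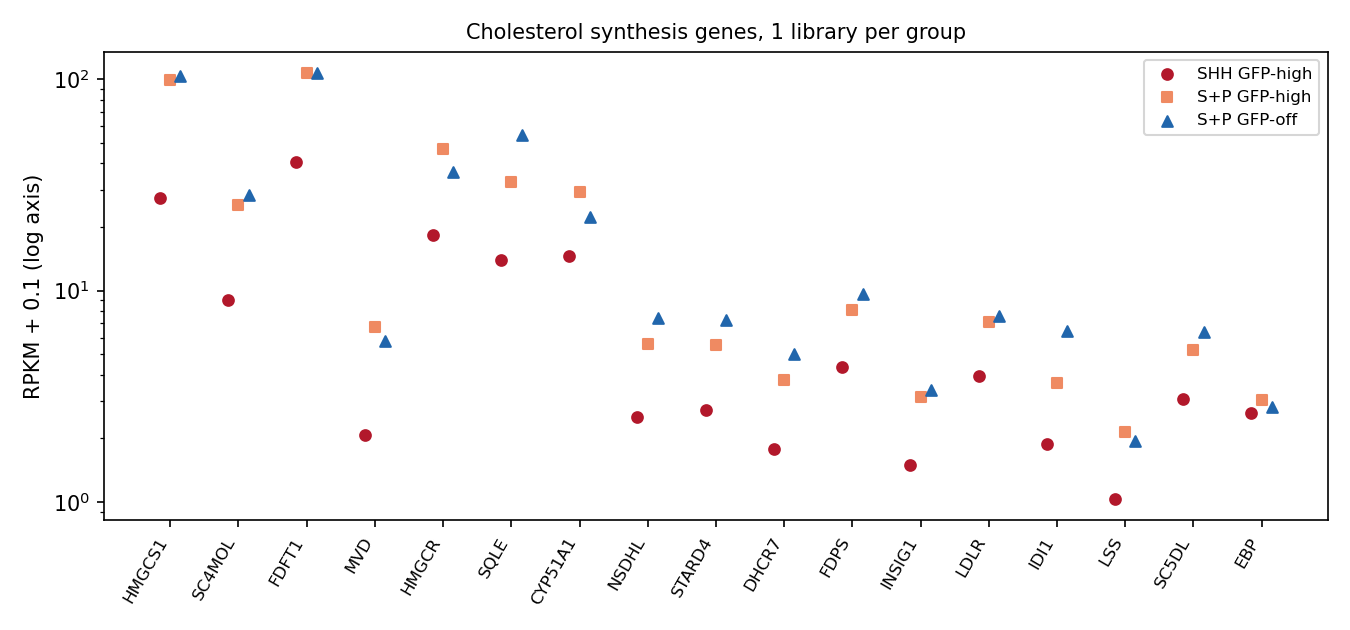
RPKM + 0.1 (log axis) of 17 cholesterol synthesis genes in the 3 libraries, 1 point per library. HMGCS1 lies at 27.2 RPKM in SHH GFP-high, 98.6 RPKM in S+P GFP-high and 104 RPKM in S+P GFP-off.

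In the mesenchyme and neural crest list, 2 of 5 measured genes were at least 2-fold lower in SHH and none higher, COL1A1 (-1.40) and COL3A1 (-1.11), with a list median of -0.91. By net reads 8 of 11 were lower, with a median of -2.66, and without the 100 most abundant genes 4 of 7; a pseudocount of 5 RPKM left none, with a median of -0.27. Of 7 glial genes 3 were lower, among them S100B (-1.70) and SOX10 (-1.09), a factor of crest and oligodendrocyte lineages, and none with a pseudocount of 5 RPKM. SOX10 had 0 reads in SHH and 102 in S+P, at least 54.4-fold lower against a floor of 3 reads in the SHH library. FN1 (-1.94), IGFBP5 (-1.82) and SFRP2 (-1.45) were also among the 12 lowest.

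All 25 measured cell cycle genes had positive log2 ratios and none passed 2-fold, with a median of 0.40, above all 10000 random lists, and of 0.21 with a pseudocount of 5 RPKM; TOP2A stood at 0.84 and MKI67 at 0.77. Replication-dependent histones had 3 of 30 members at least 2-fold higher, among them HIST1H2AI (1.22) and HIST1H2AL (1.10), against 6 of 29 by net reads, 7 of 30 with a pseudocount of 0.1 RPKM and none with 5 RPKM. Axon guidance and trophic receptor genes went both ways: PLXNA4 was higher (1.35) and EFNA5 (-1.36) and DCC (-1.04) lower, against 3 higher and 5 lower of 31 by net reads and none with a pseudocount of 5 RPKM. No measured member of the neural progenitor, Hedgehog, retinoic acid, voltage-gated channel, pluripotency, epithelial, endothelial, other transmitter, motor neuron disease, immediate early, hypoxia, housekeeping, ribosomal or mitochondrial lists passed 2-fold. By net reads, 5 of 8 epithelium and endoderm genes were higher and none lower, with a median of 2.08, and 2 of 11 retinoic acid genes were higher. Lower by net reads were 3 of 17 voltage-gated channels, 5 of 6 genes of other spinal neurons, and 3 of 8 other transmitter genes, of which 1 was higher. A pseudocount of 0.1 RPKM gave 1 higher epithelium and endoderm gene and 1 lower neural progenitor gene. By net reads, neural progenitors had 1 of 18 in each direction, hypoxia genes 1 of 12 higher and ribosomal protein genes 1 of 80 lower. PTCH1 stood at 10.3 RPKM in SHH and 10.4 RPKM in S+P, and GLI1 had 5 and 2 reads. Further high genes were NPPB (1.85), RGS16 (1.27), IGF2 (1.26), CDH13 (1.13), H19 (1.12), PAQR8 (1.07) and DLG2 (1.03), and LYPD1 (-1.32) was among the low ones.

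SHH GFP-high against S+P GFP-off differed in both protocol and fraction and was read only beside the S+P comparison. Of 11747 genes that entered, 376 were at least 2-fold higher and 655 lower, with a median log2 ratio of -0.23; median-ratio scaling gave 548 and 378, and upper-quartile scaling 535 and 392. STMN2 stood at 264 RPKM in SHH GFP-high, DCX at 89.2 RPKM and NCAM1 at 58.6 RPKM, against 21.4, 13.4 and 8.94 RPKM in GFP-off. SOX2 stood at 3.49 RPKM and VIM at 30.3 RPKM, against 19.9 and 138 RPKM.

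Among 11543 genes that entered both comparisons with GFP-off, 290 were at least 2-fold higher in both GFP-high libraries. That was 74.6% of the 389 S+P calls and 82.2% of the 353 SHH calls among these genes. Lower in both were 413 genes, 68.4% of 604 S+P calls and 63.1% of 655 SHH calls. Unchanged simulated libraries sharing 1 control gave means of 5.77 and 6.33 genes, and independent lists of these sizes would share 11.9 and 34.3. The simulated noise was centred on its median, so it left out any scaling offset between the GFP-high and GFP-off libraries. Part of the overlap may come from the shared GFP-off library, which could not be split.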

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

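The alternatives with at least 20 net reads and with the whole counting interval past 2-fold were chosen after seeing the data. With 1 library per group, the limits are depth and the absence of replicates. No paired analysis was possible because each group holds 1 library. Of 80 gene counts recomputed under settings that could move them, 23 stayed within 1.5 times the main count. All 36 counts of lists standing apart from random lists did so too, but the lists behind them changed. In S+P GFP-high against GFP-off, the Hedgehog list moved from percentile 0.355 to 9.025 with a pseudocount of 5 RPKM. In SHH against S+P GFP-high, the cholinergic list moved from 98.83 to 53.2 without the 100 most abundant genes. Higher and lower counts are given in that order for S+P GFP-high against GFP-off (main 404 and 604), SHH against S+P GFP-high (27 and 40), SHH GFP-high against GFP-off (376 and 655) and shared by both GFP-high libraries (290 and 413). With a pseudocount of 0.1 RPKM they were 757 and 1375, 114 and 161, 726 and 1424, and 540 and 1007. With a pseudocount of 5 RPKM they were 118 and 101, 2 and 8, 109 and 138, and 88 and 86. With a filter of 5 RPKM, which tests fewer genes, they were 245 and 353, 15 and 20, 220 and 396, and 182 and 268. With a 4-fold threshold they were 58 and 24, 1 and 1, 53 and 55, and 39 and 20. With at least 20 net reads they were 1123 and 2216, 418 and 310, 1307 and 2292, and 856 and 1612. With the whole counting interval past 2-fold they were 676 and 1018, 77 and 99, 725 and 1230, and 512 and 726. Median-ratio scaling gave 382 lower genes in S+P, 378 in SHH against GFP-off and 241 shared; upper-quartile scaling gave 399, 392 and 252. Without the 100 most abundant genes 46 and 65 genes differed between the GFP-high libraries and 640 were lower in both. Leaving out the filter could not move a gene count, since a gene below 1 RPKM in both libraries cannot reach 2-fold with 1 RPKM added. A higher fold threshold or filter admits fewer genes by construction; the cause of the other shifts was not tested. The 4-fold threshold gives no list medians, and the counting interval alternative was not run on lists.

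Of 452 list medians recomputed, 379 stayed within the 95% bootstrap interval over members, 67 lay outside it, and 6, of lists that stood apart from random lists, changed sign, all before subtracting the median of all genes. The retinoic acid median in S+P GFP-high against GFP-off was -0.017 without a filter, -0.16 without the 100 most abundant genes and -0.22 with at least 20 reads; relative to all genes it was -0.017, 0.086 and 0.0094, so that the sign changed only without a filter. The cholinergic median in SHH against S+P GFP-high was -0.038, -0.075 and -0.031 under those settings, and -0.038, -0.023 and 0.019 relative to all genes. The cause was not tested.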

Other observations

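The tests below, except that of gene length, GC content and expression level, were chosen after the result was seen, and the genes named in this paragraph were picked by their values. By net reads, 5 of 6 genes of other spinal neurons were at least 2-fold lower in SHH GFP-high than in S+P GFP-high, and of 8 other transmitter genes 3 were lower and 1, SLC6A4, higher (106 reads against 32). Among those lower, in S+P against SHH GFP-high, TAL1 had 60 reads against 4, PAX2 63 against 41, VSX1 64 against 30, GAD1 99 against 28 and GAD2 53 against 8. In S+P GFP-off they had 10, 5, 49, 35 and 18 reads. Epithelium and endoderm genes had 5 of 8 higher in SHH GFP-high: CDH1 had 129 reads in SHH GFP-high, 3 in S+P GFP-high and 13 in S+P GFP-off, and KRT19 had 37, 2 and 6. IGF2 and H19, neighbours in an imprinted region, were both higher in SHH than in S+P GFP-high, 3.02-fold (2.70 to 3.38) and 2.72-fold (2.26 to 3.29).

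Cholesterol synthesis genes were lower in SHH GFP-high than in S+P GFP-high, with a list median of -0.87 (bootstrap interval over members -1.32 to -0.74). Against scaling as the whole cause, the highest median over 3 other scalings was -0.77 (-1.23 to -0.67). After a fit on gene length, GC content and expression level over all entering genes, the median was -0.85 (-1.20 to -0.69) in 18 members. GFP-off cells in the S+P GFP-high sort, at the upper quartile of the share seen in other genes, would give a median of -0.23. As a hypothesis, a difference of the whole culture may be involved. The list median of SHH GFP-high over S+P GFP-off was -1.14 (-1.38 to -0.84). Relative to the median of all genes it was -0.91, against -0.82 for SHH over S+P GFP-high. But protocol and culture batch cannot be told apart with 1 library per group and no SHH GFP-off library analysed here.

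Mesenchyme genes were higher in S+P GFP-high than in SHH GFP-high. Taking SHH GFP-high as the baseline, 13 list members stood at a median of 0.342 of the GFP-off level (0.293 to 0.362). Another 50 genes, at least 4-fold lower in SHH GFP-high than in GFP-off, stood at a median of 0.0782 (quartiles 0.0341 and 0.141). An even carry-over of GFP-off cells would give like shares. But the list was taken up because its genes were higher in S+P GFP-high, and the other genes were chosen without that condition. The gap therefore does not decide against an even carry-over. A candidate explanation, not decided here, is 1 kind of mesenchymal cell in the S+P GFP-high fraction, which the sort by GFP should remove. The upper quartile of the shares was 1.23 times the lower, and 9 of 13 lay between 0.25 and 0.4. That range was set after the values were seen and the quartiles leave out both ends of the spread, so neither figure decides. Outside that range were ACTA2 (0.0815), TWIST1 (0.0826), POSTN (0.106) and TFAP2A (0.674), and the most abundant of the 13 in S+P GFP-high, ACTA2 and COL1A1, stood at 2.42 and 2.30 RPKM; THY1, which neurons also express, was not among the 13. Protocol and culture batch stay open.

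HOXB8, HOXB9 and PHOX2A were higher in SHH GFP-high than in S+P GFP-high. Against cells like the S+P GFP-off fraction in the SHH sort, each gene was also higher than in S+P GFP-off. The smallest fold was 4.05 (3.59 to 4.57), for HOXB9. No SHH GFP-off library was analysed here, so a carry-over of GFP-off cells of the SHH cultures stays open. As a hypothesis, a shift to a more caudal identity may be involved for HOXB8 and HOXB9. Such a shift would not account for PHOX2A, a factor of cranial visceral motor neurons. HOXC6, HOXC8 and HOXC9 together had 21 reads in SHH and 34 in S+P (0.386-fold, 0.213 to 0.685). That is the opposite direction, but in genes near the floor, so it decides nothing. Protocol and culture batch stay open, untested.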
